A study of Mus musculus with 7 samples.

How the data were processed

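RNA was measured in 7 libraries of LT-HSCs, 4 from WT and 3 from Srp72+/- aged mice, and each library was placed in its group by its title and genotype label. Per the labels' protocols, marrow cells were sorted into lysis buffer, RNA was extracted with a column kit, amplified with the NuGEN Ovation RNA-seq V2 system and made into Illumina libraries with a TruSeq V2 kit. Whole-transcript amplification of small inputs can enlarge the differences between libraries, and reads without molecular identifiers are not independent molecules, so limits from read numbers cover counting error only. The deposited tables hold estimated counts of reads per transcript (expected counts), which per the submitters' processing notes were made with Salmon 0.12.0. Those notes also name the builds mm10 and GRCm38.p6. The transcript release and the options for bias correction are not given in the sources used here. The deposited tables also hold TPM values and effective lengths per transcript, which served here only to weight transcript lengths.

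Of 136288 transcripts, 136176 matched GENCODE M21 on GRCm38, and the 112 without a match held between 0.0413% and 0.0622% of the reads and were left out. Estimated counts were summed over the transcripts of a gene, giving 53458 genes, and rounded to whole numbers. Coordinates are those of GENCODE M21. Reads shared by paralogs or pseudogenes were divided by the authors' tool, so values of close copies (Srp54a, Srp54b and Srp54c, the globin genes, Hspa1a and Hspa1b, and pseudogenes) are uncertain. The strand setting is not given in the sources used here, so overlapping antisense genes are uncertain too. The total per library was between 18054322 and 35247472 estimated reads, and 3 counts, taken as the floor, equal between 0.091 and 0.192 CPM.

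Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 20314. Libraries were scaled by TMM, and the genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 (robust dispersion estimates, no covariate) with Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3. Fold changes are Srp72+/- against WT. For Srp72 a two-sided exact permutation test of log2 CPM over the 35 splits was added. The 27 gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the lists), with camera with an estimated correlation, with fry, and with exact permutation of list means. Log2 CPM values used a prior count of 2. The list member Srpra was matched through its synonym Srpr, and a duplicated symbol was given to the identifier with the most reads. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

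Named genes were protein-coding genes other than unnamed gene models. Srp72 and the SRP list were always named. In each direction up to 10 genes past the threshold with the largest fold change, with groups that do not overlap and with a mean of at least 5 CPM were to be named. As 0 passed, the 6 genes with the smallest unadjusted p that met the other conditions were named in each direction. From each described list the 3 tested members with the smallest p were chosen, and some of these are left out of the text.

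The procedure was tested on simulated data, drawn from the means, depths and dispersions of these libraries in 3 simulations with 200 changed genes each. In the simulated comparison of 4 WT against 3 Srp72+/- libraries (20314 genes), genes of at least 5 CPM were recovered in 0.85% of cases at 2-fold, 19.3% at 4-fold and 54.8% at 8-fold, with 5 false calls in all. With WT 2 left out (19856 genes), genes of at least 5 CPM were recovered in 3.79%, 56.2% and 76.6% of cases at these folds, and all changed genes in 2.5%, 35.8% and 57.1%, with 25 false calls. A list shifted by -1 on the log2 scale was called in 3 of 3 simulations, and 2 calls fell on other lists with 7 libraries. Genes in these simulations were drawn independently, so they do not test the effect of correlation between genes.

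Alternatives were RLE (DESeq2 size factors) and upper-quartile scaling, no filter, a stricter filter (a mean of at least 10 counts and 1 CPM in 3 libraries), a transcript length offset, protein-coding genes only, a non-robust fit, an FDR of 0.1, DESeq2 1.42.0, voom with sample quality weights in limma, the replicate number as a block, each library left out in turn, and for the lists members of at least 1 CPM. Chosen after seeing the data were a fit without WT 2 and Srp72+/- 1 and a fit with a mature cell score as a covariate, which is the mean log2 CPM of the neutrophil, erythroid and B cell lists in each library. The list tests with an estimated correlation in sets without 1 library were also chosen after seeing the data. So was the permutation of list means without WT 2. Unusual WT libraries were sought with Dixon's ratio in library measures, list means and named genes, with 0.1 CPM added before taking the log2 of single genes.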

Results

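The series measured gene expression by RNA sequencing in long-term haematopoietic stem cells (LT-HSCs), the rare marrow cells that sustain blood formation over long periods. Cells were sorted from the bone marrow of aged C57/BL6 mice by surface markers, as cells lacking mature lineage antigens, Flt3 and CD48 and carrying Sca1, cKit and CD150. There were 4 wild-type (WT) mice and 3 mice heterozygous for Srp72 (Srp72+/-), with 1 library per mouse. The libraries held 18054322 estimated reads in WT 1, 18499250 in WT 2, 19776161 in WT 3 and 21826533 in WT 4. The Srp72+/- libraries held 18370936 reads in Srp72+/- 1, 19752324 in Srp72+/- 2 and 35247472 in Srp72+/- 3. Mitochondrial ribosomal RNA took between 26.3% (WT 2) and 31.4% (WT 1) of the reads. The comparison asks how the loss of 1 Srp72 allele alters the transcriptome of aged LT-HSCs.

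Srp72 encodes a protein subunit of the signal recognition particle (SRP), the ribonucleoprotein that guides ribosomes making secretory and membrane proteins to the endoplasmic reticulum. Srp72 (ENSMUSG00000036323, chromosome 5, 76974683 to 76999937 on the plus strand of GRCm38) measured 99.6, 136.6, 103.0 and 88.4 CPM (read counts scaled to a common library size) in WT 1 to WT 4, and 71.9, 45.7 and 109.8 CPM in Srp72+/- 1 to Srp72+/- 3. The means were 106.9 ± 20.7 CPM (SD, n = 4) in WT and 75.8 ± 32.3 CPM (SD, n = 3) in Srp72+/-. Expression in Srp72+/- was thus 0.709 of WT (95% confidence interval 0.427 to 1.18), a log2 fold change of -0.50 with a standard error of 0.32, and the groups overlapped because Srp72+/- 3 lay above 3 of the WT libraries. The difference did not pass the test (edgeR quasi-likelihood test, adjusted p = 0.9998, unadjusted p = 0.159), and a two-sided exact permutation test gave p = 0.2, where 35 splits of the libraries allow no p below 0.0286. The highest value was that of WT 2, a library low in HSC transcripts as described below, and Srp72+/- 3 lay above the other WT libraries. Without Srp72+/- 3 the log2 fold change was -0.87, and without Srp72+/- 2 it was -0.25. With correction for the length of the transcripts used it was -0.32. The part of the gene altered in these mice is not given in the sources used here, so reads over the whole gene are an incomplete check of the genotype labels.

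None of the genes of the other SRP proteins and the SRP receptor passed the test between the genotypes. Of 9 tested members of this list, 3 had higher and 6 had lower fitted values in Srp72+/-, with a median log2 fold change of -0.08, and 0 passed a false discovery rate (FDR) of 0.05. Srp14 measured 40.9 ± 7.0 CPM (SD, n = 4) in WT and 32.5 ± 7.4 CPM (SD, n = 3) in Srp72+/-. Srp68, which encodes the partner that SRP72 binds in the particle, measured 53.2 ± 10.6 and 46.2 ± 13.8 CPM. Srpr, the receptor subunit at the endoplasmic reticulum, measured 57.6 ± 6.1 and 51.7 ± 8.1 CPM. The log2 fold changes of the remaining members were 0.23 for Srp19, 0.24 for Srp54b, -0.10 for Srprb, -0.08 for Srp54c, 0.04 for Srp9 and -0.04 for Srp54a. The Srp54 copies are close paralogs on chromosome 12, so the division of reads among them is uncertain. The list as a whole had an adjusted p = 0.719 in the camera test of limma. Its direction turned to higher without WT 2 (median 0.06) and without Srp72+/- 2 (median 0.03), and its median was -0.19 without WT 3, -0.12 without WT 4 and -0.22 without Srp72+/- 3.

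The libraries differed strongly in their content of stem cell and mature blood cell transcripts, and WT 2 stood apart. The mean log2 CPM of 26 HSC identity genes was 2.07 in WT 2, against 6.44, 6.33 and 6.61 in WT 1, WT 3 and WT 4 and 5.55, 6.21 and 5.96 in Srp72+/- 1 to Srp72+/- 3. Procr, which encodes the endothelial protein C receptor that marks HSCs, was at 0.064 CPM in WT 2 and between 19.4 and 43.8 CPM in the other WT libraries. Hlf, a stem cell transcription factor gene, was at 13.1 CPM against 407 to 655 CPM. Slamf1, which encodes the sorting marker CD150, was at 4.66 CPM in WT 2 against 61.1 to 72.8 CPM. Transcripts of mature cells ran the other way. S100a8, a neutrophil calprotectin gene, was at 8421 CPM in WT 2 and between 19.2 and 1985 CPM in the other WT libraries. Hbb-bs, a beta-globin gene, was at 5008 CPM against 73.8 to 185 CPM, and the immunoglobulin gene Igkc at 7328 CPM against 17.7 to 538 CPM. Among the Srp72+/- libraries, Srp72+/- 1 had the highest levels of these 3 transcripts, with S100a8 at 2355 CPM, Hbb-bs at 3481 CPM and Igkc at 3036 CPM. These marker genes were picked from the fixed lists after their values were seen.

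**Figure D1:**
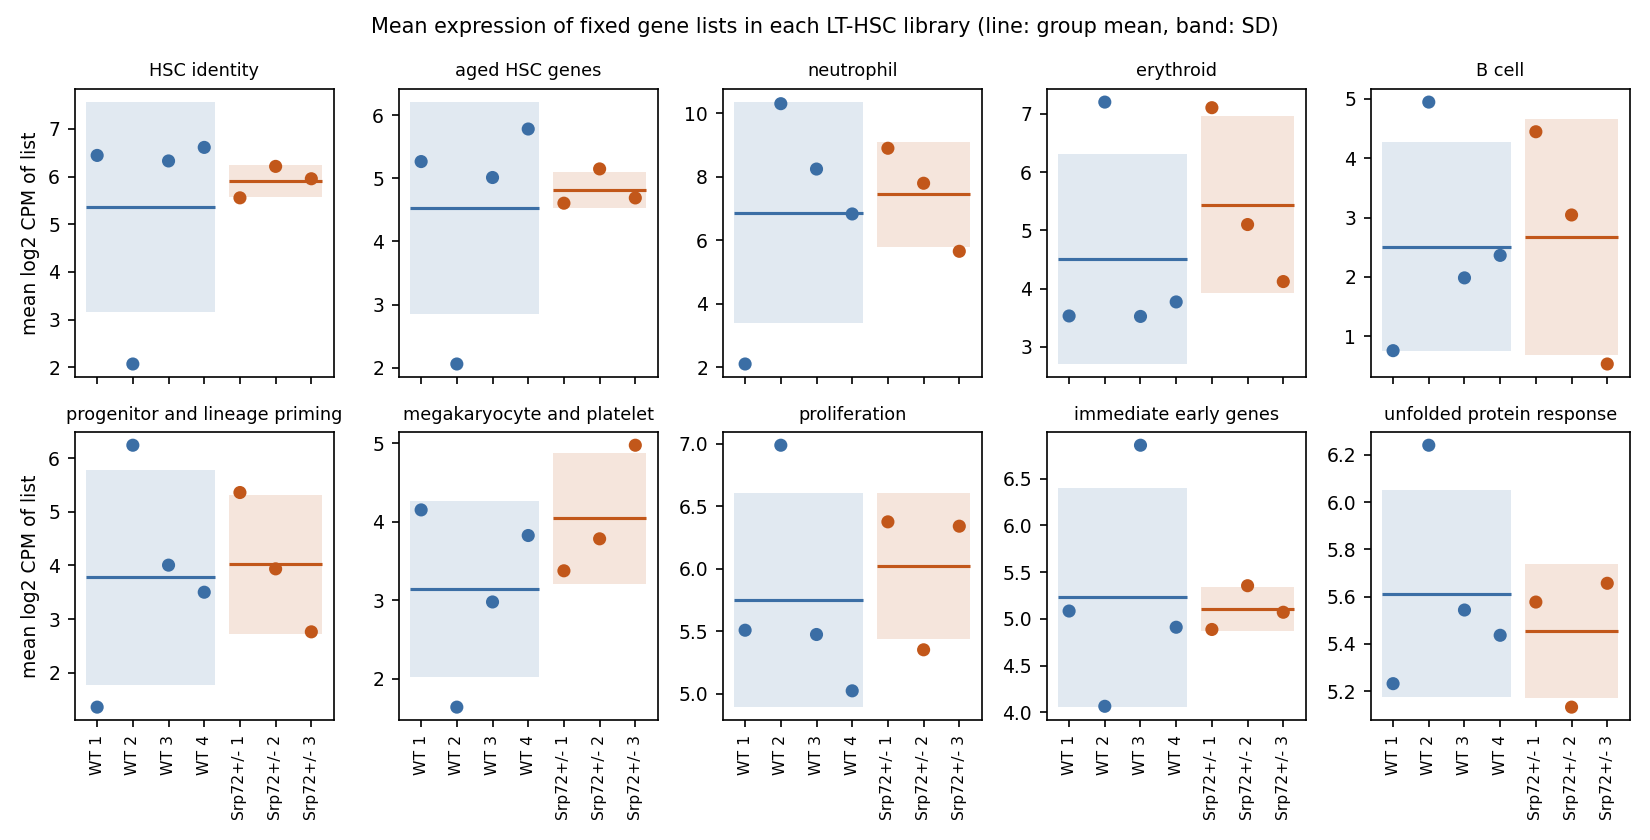
Mean log2 CPM (y axis) of 10 fixed gene lists in each of the 7 libraries (x axis), with WT in blue and Srp72+/- in orange. Each point is 1 library, horizontal lines are group means and shaded bands are 1 SD. WT 2 has an HSC identity mean of 2.07 while every other library lies between 5.55 and 6.61.

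At the level of single genes, 0 of 20314 tested genes differed between Srp72+/- and WT at an FDR of 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, smallest adjusted p = 0.9998). At an unadjusted p below 0.05 there were 365 genes, 205 higher and 160 lower in Srp72+/-, where 1016 would be expected by chance. DESeq2 called 9 genes, 5 higher and 4 lower. The libraries of the groups did not overlap for 725 genes, or 3.57% of those tested, where chance gives 5.71%. The biological coefficient of variation was 0.628. In simulated data with the spread of these libraries and 20314 genes, the test recovered 0.5% of genes changed 2-fold, 10.95% of those changed 4-fold and 34.3% of those changed 8-fold. Among genes of at least 5 CPM it recovered 0.85%, 19.3% and 54.8% at these folds, so most differences of up to 4-fold were not detectable. Without WT 2 and Srp72+/- 1, the pair with the most mature cell transcripts, 0 genes passed and 849 had an unadjusted p below 0.05.

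None of the genes named by the fixed rule passed the threshold, and they are given for their size and their separation between the groups. The smallest unadjusted p among them belonged to Cd38 (chromosome 5, 43868553 to 43912375), which encodes a surface enzyme that consumes NAD. Cd38 measured 28.5 ± 5.1 CPM (SD, n = 4) in WT and 10.2 ± 1.1 CPM (SD, n = 3) in Srp72+/-, with lower values in every Srp72+/- library than in any WT library. Its log2 fold change was -1.49 with a standard error of 0.28 (edgeR, unadjusted p = 0.000565, adjusted p = 0.9998). It passed when adjusted over the list alone among 25 aged HSC genes (edgeR, adjusted p = 0.0141), and DESeq2 called it over all genes (adjusted p = 0.000486). Other genes with lower values were Tmem173, which encodes the cytosolic DNA sensing adaptor STING, at 34.1 ± 6.9 CPM in WT and 16.5 ± 2.5 CPM in Srp72+/-, and Cnih4, a cargo receptor gene of the early secretory pathway, at 33.0 ± 4.6 and 17.6 ± 1.2 CPM. The log2 fold changes of Rrs1 (ribosome biogenesis), Marcksl1 (an actin regulator) and Col1a2 (a collagen chain) were -1.08, -1.29 and -1.58.

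Genes with higher values in Srp72+/- included Mrm1, a mitochondrial ribosomal RNA methyltransferase gene, at 9.96 ± 1.96 CPM (SD, n = 4) in WT and 19.6 ± 1.8 CPM (SD, n = 3) in Srp72+/-. Mfsd8 and Tmem175, which encode lysosomal membrane proteins, measured 15.8 ± 1.6 and 27.1 ± 6.2 CPM in WT and 27.1 ± 3.7 and 46.7 ± 5.3 CPM in Srp72+/-. The log2 fold changes of Pot1b (telomere binding), Dclre1a (repair of DNA crosslinks) and Vamp2 (vesicle fusion) were 0.55, 0.80 and 0.53. The adjusted p of each was 0.9998 in edgeR.

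**Figure D2:**
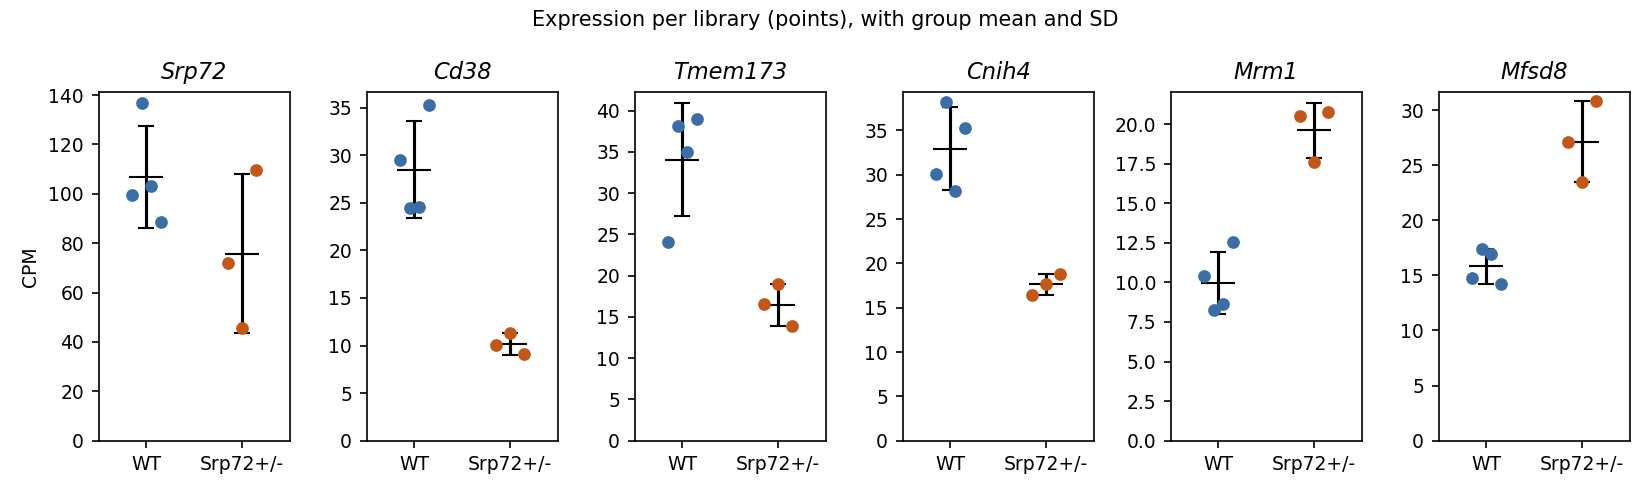
Expression in CPM (y axis) of Srp72 and 5 genes named by the fixed rule in WT (blue, 4 libraries) and Srp72+/- (orange, 3 libraries). Points are libraries, and black marks give the group mean and SD. The groups overlap for Srp72 and are separate for Cd38, Tmem173, Cnih4, Mrm1 and Mfsd8, none of which passed the FDR threshold in edgeR.

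Of 27 gene lists fixed in advance, 9 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01 between genes, 2 with higher and 7 with lower values in Srp72+/-. With a correlation estimated from the libraries 0 of the 27 passed, and 0 passed with it when any 1 library was left out (smallest adjusted p = 0.294). The highest count that passed with it in any of the 35 splits of the libraries was also 0. A count of 0 with this version thus says little about the genotypes. The directional fry test passed 0 lists as well. In every list 0 members passed the FDR over all genes, and adjusted over the list alone 0 members passed except Cd38.

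Lists of protein folding and secretion had mostly lower fitted values in Srp72+/-. For translocation into the endoplasmic reticulum and signal peptide processing, 21 of 25 tested members were lower, with a median of -0.15 (camera adjusted p = 0.0426, and adjusted p = 0.927 with an estimated correlation). Its members with the smallest p were Spcs1 (-0.49), Ostc (-0.70) and Sec11c (-0.33). For the unfolded protein response, 26 of 28 were lower, with a median of -0.24 (camera adjusted p = 0.0157, and adjusted p = 0.927 with an estimated correlation). Xbp1, the transcription factor gene of this response, measured 163.4 ± 87.3 CPM (SD, n = 4) in WT and 80.0 ± 10.7 CPM (SD, n = 3) in Srp72+/-, and Pdia3 and Ern1 had log2 fold changes of -0.51 and -0.53. Xbp1 was at 286 CPM in WT 2 and at 147 and 140 CPM in WT 3 and WT 4. In WT 1 it was at 80.4 CPM, within the Srp72+/- range of 73.1 to 92.4 CPM. For cytosolic heat shock chaperones, 16 of 17 were lower, with a median of -0.17 (camera adjusted p = 0.0157, and adjusted p = 0.927 with an estimated correlation). The smallest p belonged to Hspa1b (-2.76), Hspa4l (-0.33) and Dnaja1 (-0.33). Hspa1b, with a standard error of 1.65, rested on WT 3 (49.4 CPM), and it was at or below the floor in WT 1 (0.11 CPM) and Srp72+/- 2 (0.13 CPM). WT 2 had the highest mean of the secretion list (6.30) and of the unfolded protein response list (6.24) of the 7 libraries. Without it both lists turned to higher values in Srp72+/- (medians of 0.06 and 0.09), with a camera adjusted p = 0.814 for each. Without Srp72+/- 2 the adjusted p of these lists was 0.903 and 0.832, with medians of -0.10 and -0.23. Without Srp72+/- 1 the adjusted p of the secretion list was 0.133. The median of the secretion list was -0.34 without WT 3 and -0.32 without Srp72+/- 3, and that of the unfolded protein response list was -0.43 without WT 3, -0.39 without WT 4 and -0.38 without Srp72+/- 1. The chaperone list had a median of -0.38 without Srp72+/- 3 and an adjusted p = 0.207 without WT 2, 0.0566 without WT 3 and 0.33 without Srp72+/- 2. Proteasome subunits were lower in 22 of 31 members, with a median of -0.11 (camera adjusted p = 0.0774), with Psma3 at -0.35, Psmc4 at -0.41 and Psmd8 at 0.42. Their direction turned to higher without WT 2 (median 0.07) and without Srp72+/- 2 (median 0.03), and the median was -0.24 without WT 3, -0.19 without WT 4 and -0.30 without Srp72+/- 3.

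Among metabolic lists, sterol synthesis had lower fitted values in 18 of 22 tested members, with a median of -0.30 (camera adjusted p = 0.00729, and adjusted p = 0.344 with an estimated correlation). Insig1, a feedback regulator of the pathway, measured 23.1 ± 8.5 CPM (SD, n = 4) in WT and 11.7 ± 4.3 CPM (SD, n = 3) in Srp72+/-. The biosynthetic enzyme genes Sc5d and Cyp51 measured 20.6 ± 2.6 and 21.6 ± 5.8 CPM in WT and 12.4 ± 4.7 and 13.5 ± 2.7 CPM in Srp72+/-. Without Srp72+/- 2 the list had an adjusted p = 0.0814. Transcripts encoded by the mitochondrial genome were lower in 12 of 13 members, with a median of -0.23 (camera adjusted p = 0.00729, and adjusted p = 0.927 with an estimated correlation), with mt-Atp8 at -0.52, mt-Nd3 at -0.66 and mt-Atp6 at -0.49. Without WT 2 the adjusted p of this list was 0.108, and without Srp72+/- 2 it was 0.117. Nuclear-encoded oxidative phosphorylation genes were lower in 34 of 55 members, with a median of -0.12 (camera adjusted p = 0.0754), with Ndufa5 at -0.65 and Uqcrfs1 at -0.39. Without WT 2 their direction turned to higher, with 35 of 55 members higher and a median of 0.07, and it did so without Srp72+/- 2 (median 0.04). The median was -0.18 without WT 4, -0.04 without Srp72+/- 1 and -0.34 without Srp72+/- 3. Cytosolic ribosomal proteins were lower in 47 of 78 members, with a median of -0.06 (camera adjusted p = 0.04997, and adjusted p = 0.927 with an estimated correlation), with Rps27a at -0.34, Rps21 at -0.43 and Rpl10 at 0.45. Without WT 1, WT 3, WT 4 or Srp72+/- 2 the call of the ribosomal protein list was lost (adjusted p = 0.144, 0.395, 0.325 and 0.832). The medians there were -0.033, -0.018, -0.043 and -0.0014. Without Srp72+/- 1 the direction of this list turned to higher (median 0.16, adjusted p = 0.0929). Its median was -0.18 without WT 2 (camera adjusted p = 5.86e-05, and adjusted p = 0.903 with an estimated correlation) and -0.41 without Srp72+/- 3 (camera adjusted p = 6.05e-16, and adjusted p = 0.709 with an estimated correlation). Ribosome biogenesis genes had 21 higher and 12 lower members, with a median of 0.03 against a lower direction in camera (adjusted p = 0.495), with Rrs1 at -1.08, Nop56 at 0.48 and Tsr1 at -0.54. This direction turned to higher without Srp72+/- 1 or Srp72+/- 2 (median 0.12 for each), and the median was -0.10 without WT 3 and -0.33 without Srp72+/- 3.

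The megakaryocyte and platelet list had higher fitted values in Srp72+/- in 17 of 18 tested members, with a median of 1.004 (camera adjusted p = 0.000318, and adjusted p = 0.927 with an estimated correlation). F2rl2 had a log2 fold change of 1.53, and the platelet glycoprotein genes Gp9 and Gp1ba had values of 1.32 and 1.37. The list mean was highest in Srp72+/- 3 (4.97) and lowest in WT 2 (1.64). Without Srp72+/- 3 the median was 0.05 and the adjusted p was 0.516, and without WT 2 it was 0.0766. The erythroid list was higher in 17 of 18 members, with a median of 0.23 (camera adjusted p = 0.00939, and adjusted p = 0.927 with an estimated correlation), with Epor at 1.65, Gata1 at 0.93 and Aqp1 at 0.73. Its mean was 7.11 in Srp72+/- 1 and 7.20 in WT 2, against values between 3.52 and 5.10 in the other libraries. Without WT 2 the median of the erythroid list was 2.58, with 18 of 18 members higher (camera adjusted p = 2.15e-15, and adjusted p = 0.542 with an estimated correlation). Its median was 0.54 without Srp72+/- 2 and 0.76 without Srp72+/- 3. Without Srp72+/- 1 the direction of the erythroid list turned to lower, with 14 of 18 members lower, a median of -1.26 and an adjusted p = 0.691. Without WT 1, WT 3 or WT 4 its call was lost (adjusted p = 0.107, 0.161 and 0.152), with medians of 0.058, 0.031 and -0.00037 and with 10, 10 and 9 of 18 members higher.

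HSC identity genes had 17 lower and 9 higher fitted values in Srp72+/-, with a median of -0.14 against a higher direction in camera (adjusted p = 0.509), with Ifitm1 at -0.96, Tcf15 at 0.63 and Procr at -0.82. Genes that are high in aged HSCs had a median of 0.01 and a lower direction in camera (adjusted p = 0.857), with Cd38 at -1.49, Tm4sf1 at -1.31 and Osmr at -1.53. Both lists depended on WT 2, which had a mean of 2.06 for the aged HSC genes against 5.01 to 5.78 in the other WT libraries. Without WT 2, the HSC identity list was lower in Srp72+/- (median -0.53, camera adjusted p = 4.93e-11), the aged HSC list was lower (median -0.35, adjusted p = 1.39e-06) and the proliferation list was higher (median 0.71, adjusted p = 2.02e-16). These calls were lost with an estimated correlation, where 0 of the 27 lists passed in that set of libraries, with adjusted p = 0.542, 0.662 and 0.662. Exact permutation of the list means in that set gave an unadjusted p = 0.1 for HSC identity and for the erythroid list. It gave 0.2 for aged HSC genes and 0.3 for proliferation. The smallest p possible there is 0.1, so this test could not reach 0.05. The HSC identity median turned to 0.11 without WT 4, with 15 of 26 members higher, and it was -0.09 without WT 1 and without WT 3, -0.05 without Srp72+/- 1, -0.28 without Srp72+/- 2 and -0.21 without Srp72+/- 3. In the set without WT 2 the mature cell lists moved as well, with 18 of 18 erythroid, 15 of 15 neutrophil and 10 of 10 B cell genes higher in Srp72+/-, and Srp72+/- 1 had the highest mature cell score (6.82, against 2.13 to 5.31 in the other libraries). With all libraries, proliferation genes were higher in 23 of 31 members, with a median of 0.14 (camera adjusted p = 0.0884), with Mcm2 at 0.58, Mcm7 at 0.35 and Mcm6 at 0.29. HSC surface receptors and adhesion proteins had a median of -0.14 (camera adjusted p = 0.91), with Epor at 1.65, Itga2b at 0.98 and Tgfbr1 at -0.43.

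Lists of other marrow cells varied more between libraries than between genotypes. The neutrophil list had a mean of 10.3 in WT 2, 8.90 in Srp72+/- 1 and 2.10 in WT 1, and its fitted values were lower in 15 of 15 members, with a median of -0.73 (camera adjusted p = 0.857), with Itgam at -0.80, S100a8 at -1.30 and Lcn2 at -1.18. Progenitor and lineage priming genes had a median of -0.42 (camera adjusted p = 0.745), with Prtn3 at -1.06, Ms4a3 at -1.62 and Ctsg at -1.28. Without WT 2 the neutrophil and priming lists turned to higher values (medians of 0.83 and 0.88, camera adjusted p = 0.00403 and 0.00246, and adjusted p = 0.887 for each with an estimated correlation). The neutrophil median was -1.14 without WT 1, -1.64 without Srp72+/- 1 and -0.27 without Srp72+/- 3, and the priming median was -0.76 without WT 1, -0.73 without WT 4 and -1.38 without Srp72+/- 1. Monocyte and macrophage genes had a median of -0.48 (camera adjusted p = 0.509), with C1qc at 1.26 and C1qa at -1.53. C1qa lay between 0.159 CPM (Srp72+/- 1), at the floor, and 3.26 CPM (WT 2). The B cell list had a median of -0.37 against a higher direction in camera (adjusted p = 0.884), with Ms4a1 at 2.09, Cd79b at 0.65 and Ebf1 at -0.93. The T and NK cell list had a median of -0.37 (camera adjusted p = 0.614), with Klrb1c at -1.10, Lck at -0.46 and Trac at -1.34. Marrow stroma and endothelium genes had a median of -0.48 (camera adjusted p = 0.495), with Col1a2 at -1.58, Col1a1 at -2.77 and Pdgfrb at -1.06. Without WT 2 the medians of the monocyte, B cell, T and NK cell and stroma lists were 0.62, 1.29, 0.36 and 0.68, with 10 of 10 B cell genes higher in Srp72+/- (camera adjusted p = 0.0966, 0.0565, 0.384 and 0.814), where camera gave the stroma list a lower direction against its median.

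Several lists short of the threshold passed it in camera when 1 library was left out, and 0 of these calls held with an estimated correlation. The proteasome and oxidative phosphorylation lists were lower without WT 1 (adjusted p = 0.0415 and 0.0216), WT 3 (0.00765 and 0.0155), WT 4 (0.0161 and 0.0133) or Srp72+/- 3 (3.91e-05 and 3.75e-08), and ribosome biogenesis was lower without Srp72+/- 3 (adjusted p = 1.29e-05). HSC identity had a higher direction in camera without WT 1 or WT 4 (adjusted p = 0.0234 and 0.0108), and proliferation was higher without Srp72+/- 2 (adjusted p = 1.61e-05). The neutrophil and monocyte lists were lower without WT 1 (adjusted p = 3.05e-05 and 0.00603), and the priming list was lower without WT 1 or Srp72+/- 1 (adjusted p = 0.00387 and 0.0286). The B cell list had a higher direction in camera without Srp72+/- 3 (adjusted p = 0.0368), and apoptosis regulators were lower without WT 4 (adjusted p = 0.0383). Other lists turned their direction in camera without passing (adjusted p between 0.0678 and 0.985). In several of these sets the median fitted fold change kept the other sign than the direction in camera. With 1 library left out the lowest and highest medians were -0.83 and 0.62 for the monocyte list, -1.65 and 1.29 for B cells, -0.92 and 0.36 for T and NK cells and -0.72 and 0.68 for stroma. They were -0.35 and 0.17 for aged HSC genes, -0.15 and 0.71 for proliferation, -0.17 and -0.08 for surface receptors, -0.26 and 0.02 for NF-kB genes, -0.10 and 0.04 for p53 targets and -0.31 and -0.05 for apoptosis regulators. To higher turned the aged HSC list without WT 1, WT 3, WT 4 or Srp72+/- 1, the surface receptor list without WT 4 or Srp72+/- 2, and the priming list without Srp72+/- 2 or Srp72+/- 3. The same held for the neutrophil list without WT 3 or Srp72+/- 3, the monocyte list without WT 2 or Srp72+/- 2, the T and NK cell list without WT 2 and the stroma list without Srp72+/- 3. It also held for the NF-kB list without WT 2, WT 3 or Srp72+/- 2 and for p53 targets without WT 3. To lower turned the B cell list without WT 1, WT 3 or Srp72+/- 1 and the proliferation list without WT 4 or Srp72+/- 3.

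Immediate early genes were lower in 19 of 22 members, with a median of -0.49 (camera adjusted p = 0.0382, and adjusted p = 0.927 with an estimated correlation). Fos measured 385 ± 347 CPM (SD, n = 4) in WT and 170 ± 28 CPM (SD, n = 3) in Srp72+/-, and Egr2 and Junb had log2 fold changes of -2.02 and -0.72. Egr2 was near the floor, with at most 2.45 CPM (WT 3) and 0 CPM in Srp72+/- 1. The list mean was 6.86 in WT 3 and between 4.06 and 5.35 in the other libraries. Without WT 3 the direction of this list turned to higher, with an adjusted p = 0.0987, and without Srp72+/- 1 or Srp72+/- 2 the adjusted p was 0.238 and 0.0814. The remaining lists stayed short of the threshold. Interferon response genes had a median of 0.06 (camera adjusted p = 0.871), with Tap1 at 0.72, Irf7 at -0.60 and Ifi47 at 0.83. Their direction turned to lower without WT 2 (median -0.07) and without Srp72+/- 3 (median -0.27, with 20 of 28 members lower), and the median was 0.11 without WT 4 and 0.17 without Srp72+/- 2. NF-kB and inflammatory genes had a median of -0.06 (adjusted p = 0.857 in camera), with Il1b at 1.78, Nfkbie at 0.87 and Relb at -1.01. Targets of p53 had a median of -0.05 and a mean of 0.02 (adjusted p = 0.91 in camera), with Eda2r at 1.67, Plk3 at -0.62 and Xpc at -0.23. Apoptosis regulators had a median of -0.19 (adjusted p = 0.0959 in camera), with Casp9 at -0.71, Diablo at 0.44 and Bcl2l11 at -0.57. Fitted fold changes and differences of library means on the log scale can point in opposite directions here. For example the neutrophil list mean was 6.87 ± 3.48 (SD, n = 4) in WT and 7.45 ± 1.65 (SD, n = 3) in Srp72+/-, while its median fitted fold change was negative.

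**Figure D3:**
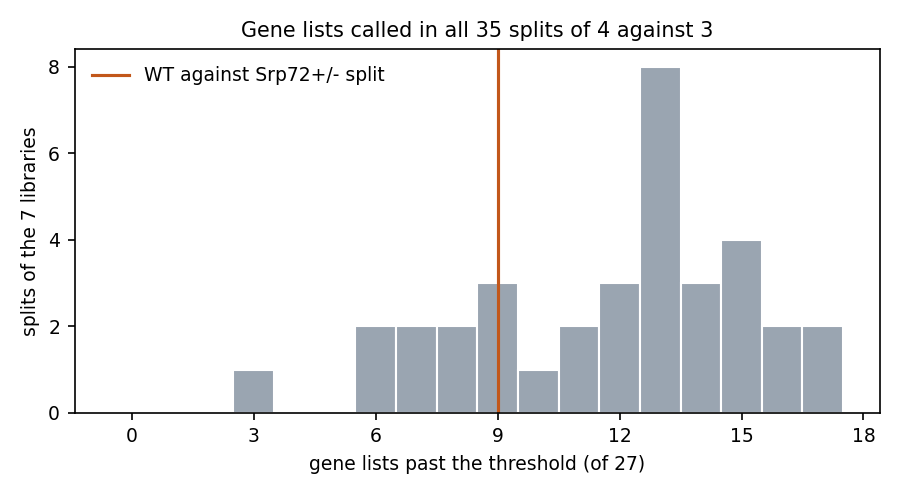
Number of gene lists of 27 past the camera threshold with the preset correlation (x axis) in each of the 35 ways to divide the 7 libraries into 4 and 3, as a histogram of splits (y axis). The vertical line marks the 9 lists of the WT against Srp72+/- split, and the splits range from 3 to 17 lists.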

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

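The tests of WT 2 and of the correlation among list members, the count of splits for single genes, the correlation across libraries, the fit of Cd38 with the mature cell score and the test of the interval between Cd38 and Srp72 were chosen after the results were seen. Among 55 measures in the 4 WT libraries, 4 had 1 library far from the other 3, where chance gives about 2.8. WT 2 was the library in 3 of the 4. Its HSC identity mean of 2.07 log2 CPM lay below the next value of 6.33, its erythroid mean of 7.20 above the next value of 3.77, and its nuclear-encoded oxidative phosphorylation mean of 5.48 above the next value of 4.91. In WT 3 the ribosome biogenesis mean of 4.996 lay below the next value of 5.16.

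WT 2 was low in HSC genes and high in genes of mature cells. Lower depth is argued against, since WT 2 held 18499250 reads against 18054322 in WT 1, and since 64.0% of the HSC identity genes of at least 5 CPM lay under 0.1 of the mean of the other WT libraries, against 4.00% of all 11665 tested genes of that level. RNA from other marrow cells stays open and is not decided by these values. In WT 2, 5 of the 5 mature cell lists (neutrophil, erythroid, B cell, T and NK cell, monocyte and macrophage) lay above the other WT libraries. S100a9 was at 11854 CPM and Igkc at 7328 CPM, although the sort excludes cells with mature lineage markers. The count of mature cell lists restates the pattern and is no test of its source. WT 2 also had the highest means of the progenitor and lineage priming list (6.24, with Mpo at 5858 CPM) and of the proliferation list (6.99). A library made from another cell fraction would give the same picture and was not tested, and the design names no biological difference among WT mice. Across the 7 libraries the mature cell score and the HSC identity mean had a Pearson r of -0.71 (permutation p = 0.0399) and a Spearman rho of -0.71 (permutation p = 0.0881), in a family of 1 relation. Without WT 1 and WT 2, the libraries farthest from the median score, r was -0.57 (permutation p = 0.292) and rho -0.40 (permutation p = 0.517), and without WT 2 alone r was -0.62 (permutation p = 0.188) and rho -0.54 (permutation p = 0.297). The relation was thus not detectable without them, in fewer libraries.

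The 9 lists past the threshold are no more than other groupings of the same libraries give. As many lists passed in 28 of the 35 splits, the real one included, and the highest other split gave 17, so chance is not excluded. For 8 of the 9 lists the estimated correlation between members was between 0.23 and 0.81, above the preset 0.01. With it 0 of these 8 lists passed. The highest count of lists that passed with it in any of the 35 splits was also 0. Losing these calls thus cannot show whether correlation among the members accounts for them. For sterol synthesis the estimated correlation of -0.02 (-0.0174) is below the preset value. Its unadjusted p in camera still rose, from 0.000569 with the preset value to 0.0127 with the estimated correlation. The latter became 0.344 over the 27 lists. Exact permutation of its list mean gave an unadjusted p = 0.114, the lowest of the 27 lists. An effect of the genotype on sterol synthesis stays open and untested beyond this comparison.

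For single genes, the real split gave 0 genes, as many or more came in 35 of the 35 splits, and the highest other split gave 3. Every split reaches a count of 0, so this comparison decides nothing about chance. That split set WT 2, Srp72+/- 1 and Srp72+/- 2 against the rest. Up to 2297 genes had an unadjusted p below 0.05, in the split that set WT 2, Srp72+/- 1 and Srp72+/- 3 apart. The real split had 365, and 6 of the 35 splits had fewer. Some other divisions thus separated the libraries more than genotype did. WT 2, Srp72+/- 1 and Srp72+/- 3 had the highest proliferation list means (6.99, 6.38 and 6.34, against 5.02 to 5.51 in the others). What set them apart was not tested.

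Cd38 was lower in every Srp72+/- library than in any WT library. With the mature cell score as a covariate the log2 fold change was -1.47, a shift of 0.021 against a standard error of 0.28. Cd38 was picked for its separate groups, and the scores of the genotypes overlapped (2.13 to 7.48 in WT, 3.43 to 6.82 in Srp72+/-). This fit could thus hardly have moved the value, and it does not decide on mature cell RNA in some libraries. Cd38 and Srp72 lie on the same chromosome, and a block of linked strain sequence might alter neighbouring genes, but no excess of genes with separate groups was detectable over chromosome 5 as a whole (3.11% of 771 genes, against 2.82% of 10871 genes elsewhere), with an odds ratio of 1.11 (95% confidence interval 0.693 to 1.69, Fisher's exact p = 0.653). Between Cd38 and Srp72, 1.92% of 104 genes had separate groups, with an odds ratio of 0.675 against the other chromosomes (95% confidence interval 0.0803 to 2.52, Fisher's exact p = 1), too few genes to decide on a block that reaches from 1 gene to the other. A variant in Cd38 itself was not tested. Chance over the genes searched stays open, because 15 of the 35 splits, the real one included, held a gene with an unadjusted p as small as 0.000565. An effect of the genotype also stays open as a hypothesis.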

How the results depend on the processing

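The fits without both WT 2 and Srp72+/- 1 and with the mature cell score were chosen after seeing the data. The count of genes past the FDR was 0 in edgeR with all libraries and in all alternatives except DESeq2 (9 genes, 5 higher and 4 lower, with 160 genes lacking an adjusted p) and the fit without WT 4 (1 gene, lower). With 1 library left out the count of all genes, and that of lower genes, was between 0 and 1. The number of genes at an unadjusted p below 0.05 was 962 without WT 2, 798 with the mature cell score, 928 with voom, 552 with DESeq2 and 1133 without a filter (40992 genes). The cause of the 9 DESeq2 calls was not tested. The log2 fold change of Srp72 was negative in every alternative, from -0.25 (without Srp72+/- 2) to -0.87 (without Srp72+/- 3, unadjusted p = 0.0223), and it was -0.72 with voom (adjusted p = 0.912). Cd38 stayed between -1.37 and -1.59 in its alternatives, and its adjusted p was between 0.791 and 1 in all but DESeq2. Over 96 named genes, 1676 of 1720 alternative values kept the sign of the main value, 44 had the other sign and 1 passed the FDR. Most of these genes were chosen by their small p in the same libraries, which favours keeping the sign, so this count is no independent test.

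All values for lists are adjusted p, and except where a cause is named it was not tested. The estimated correlation ended the calls of 9 lists (0.344 for sterol synthesis and 0.927 for the others), and so did fry (0.525 and 0.998), which asks another question. With members of at least 1 CPM the ribosomal protein (0.0562) and immediate early (0.0633) calls were lost. Without a filter proteasome (0.0102), oxidative phosphorylation (0.00507) and apoptosis (0.0322) passed. The strict filter ended ER translocation (0.0547), ribosomal proteins (0.0592) and immediate early (0.0592). The length offset ended ER translocation (0.185) and heat shock (0.0524) and added oxidative phosphorylation (0.0369). With coding genes only ER translocation (0.0562), ribosomal proteins (0.0957) and immediate early (0.0545) were lost and proliferation (0.0361) passed. Without both WT 2 and Srp72+/- 1, ER translocation (0.876), ribosomal proteins (0.909) and HSC identity (2.42e-05, lower) changed direction, unfolded protein response (0.876) and heat shock (0.151) were lost, and aged HSC (0.000604, lower) and proliferation (3.78e-09, higher) passed. The mature cell score added proteasome (0.0313), oxidative phosphorylation (0.0418), HSC identity (0.00034), priming (0.0036) and neutrophil (0.0422) and ended ribosomal proteins (0.415) and immediate early (0.148). With voom and quality weights priming (0.00426, higher), neutrophil (0.000101, higher) and interferon response (0.037, lower) changed direction. It also passed proteasome (0.0281), ribosome biogenesis (0.00387), oxidative phosphorylation (0.00387), aged HSC (0.037), B cell (0.0281) and proliferation (0.000259), and lost unfolded protein response (0.179) and megakaryocyte (0.448). Voom gave WT 2 a weight of 0.327 and Srp72+/- 3 a weight of 0.434. RLE and upper-quartile scaling changed no list call.

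With 1 library left out, which also lowers the number of samples, the adjusted p ranged from 3.91e-05 to 0.884 for proteasome, 6.05e-16 to 0.832 for ribosomal proteins, 3.75e-08 to 0.832 for oxidative phosphorylation and 4.93e-11 to 0.961 for HSC identity. It ranged from 0.00246 to 0.961 for priming, 2.15e-15 to 0.691 for erythroid, 3.05e-05 to 0.961 for neutrophil and 0.00603 to 0.961 for monocyte. The range was 0.000142 to 0.903 for ER translocation, 0.00108 to 0.832 for unfolded protein response, 3.88e-06 to 0.33 for heat shock and 0.000132 to 0.117 for mitochondrially encoded transcripts. It was 1.39e-06 to 0.985 for aged HSC, 1.64e-06 to 0.516 for megakaryocyte, 2.02e-16 to 0.948 for proliferation and 5.86e-05 to 0.238 for immediate early. For apoptosis it was 0.0383 to 0.832, for sterol synthesis 0.00244 to 0.0814, for ribosome biogenesis 1.29e-05 to 0.855 and for B cell 0.0368 to 0.961.

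The deviations of same-numbered libraries of the genotypes had correlations of -0.32, -0.16 and 0.002 across genes. Those of the other pairs lay between -0.23 and 0.39, with the highest for WT 2 and Srp72+/- 1. A pairing by replicate number was thus not detectable, but larger differences between libraries could hide it, so it is not excluded. With the replicate block 0 genes passed and 139 had an unadjusted p below 0.05, the Srp72 log2 fold change was -0.65, and 12 lists passed. The block added proteasome (0.031), oxidative phosphorylation (0.0231), HSC identity (0.00143) and apoptosis (0.031), turned aged HSC to higher (0.0267) and ended ribosomal proteins (0.161) and erythroid (0.0559).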

Other observations

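Genes that DESeq2 called, and that the fixed rule does not name apart from Cd38, included several gene models with all reads in 1 genotype. Gm20431, a protein-coding model on chromosome 2 (167607850 to 167661496), had 51, 146, 55 and 189 estimated reads in WT 1 to WT 4 and 0 in each Srp72+/- library. The processed pseudogene Gm9449 had 0 reads in each WT library and 34, 17 and 155 in Srp72+/- 1 to Srp72+/- 3. Gpr45, an orphan receptor gene, had between 0 and 6 reads in the WT libraries and 52, 48 and 45 in the Srp72+/- libraries. The remaining called genes were Gm12254, Gm16464, Gm44681, Gm13316 and Gm11914. The pseudogene Gm28439, called by edgeR when WT 4 was left out (adjusted p = 0.0267), had 1335, 966 and 1790 reads in WT 1 to WT 3 and 0 in WT 4 and in every Srp72+/- library. Reads of such models are divided among similar sequences by the quantification, and these genes were chosen after their values were seen.

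The share of Srp72 reads assigned to its protein-coding transcripts was 89.0%, 83.1%, 77.7% and 63.3% in WT 1 to WT 4 and 64.4%, 55.3% and 80.4% in Srp72+/- 1 to Srp72+/- 3. Srp72+/- 2 had reads in 36728 genes, against 26921 to 28608 in the other libraries. This library also had the lowest Srp72 level (45.7 CPM). With it left out 3 lists passed in camera with the preset correlation, against 6 to 13 with any other library left out. A link between these values was not tested, and the search for unusual libraries covered WT only. Transcripts of long non-coding genes took 7.53% of the reads in Srp72+/- 2 and 7.48% in Srp72+/- 3, and between 5.46% and 6.04% in the others. Xist was between 2479 and 5705 CPM in all 7 libraries. Of the Y-linked genes, Ddx3y was at most 0.702 CPM and Eif2s3y at most 0.783 CPM. Kdm5d was between 5.65 and 11.4 CPM and Uty between 0.897 and 2.49 CPM. Cxcl12, a niche chemokine gene, was at 14.5 CPM in WT 2, between 7.57 and 9.03 CPM in the Srp72+/- libraries and between 0.359 and 1.34 CPM in the other WT libraries. Pf4, a platelet chemokine gene, was at 404 CPM in Srp72+/- 3 and at most 119 CPM elsewhere. These values were chosen after they were seen.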
